A study of Mus musculus with 6 samples.

How the data were processed

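The data were RNA-seq libraries from mouse dentate gyrus, 3 labelled cKO and 3 labelled Ctrl. Per the labels' protocols, total RNA was isolated with Trizol, and libraries were built with an NEBNext Ultra RNA kit. The authors deposited a table of raw gene counts and a table of FPKM values for the same 54040 genes and 6 libraries. Per the submitters' processing notes, HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 were used with the GRCm38 genome. Which tool made which value, the annotation release and the use of strand in counting are not given in the sources used here. The deposited counts are whole numbers that sum to a different total in each library. The table holds 239 assembled loci without a gene identifier, which took 0.155% to 0.171% of the counts and of which 192 were tested. The deposited FPKM values equal the count divided by gene length and by 1 constant per library, which lay between 99.8% and 101% of that library's count total. FPKM was used only for an alternative test.

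Samples were assigned to groups by their titles, and the columns were matched to the samples by name, with 0 columns of per-sample values left unused. Library totals were 16905361, 16794642 and 18609419 counts in cKO replicates 1 to 3 and 16920062, 16861496 and 19190101 in Ctrl replicates 1 to 3. In a single library 3 counts correspond to 0.156 to 0.179 CPM, and a ratio against a group with 0 counts used a floor of 3 counts over the whole group. No libraries were counted as duplicates, since the chi-square per degree of freedom between replicates of a group was 2.71 to 4.70 over genes with at least 20 summed counts. The highest values, 4.70 and 4.49, were those of Ctrl replicate 1 against Ctrl replicates 2 and 3. All other pairs lay between 2.71 and 3.47. Principal component 1 of log2 CPM held 28.7% of the variance, with all cKO libraries on 1 side and all Ctrl libraries on the other.

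Counts were analysed in R 4.3.3 with edgeR 4.0.16. Of the 54040 genes, 23036 had no count in any library, and filterByExpr (minimum count 10, minimum total count 15, by group) kept 16928, of which 13950 are protein-coding. Libraries were scaled by TMM, and cKO was compared with Ctrl in all 6 libraries by the quasi-likelihood F test (glmQLFit and glmQLFTest) with group as the only term. Genes with a Benjamini-Hochberg false discovery rate under 0.05 were called changed, with no bound on the fold. The standard error of a log2 fold change was taken from the fold change and the square root of the F statistic. Ythdf2 was also compared by an exact two-sided permutation test of CPM. Fold changes of summed counts on chromosome 12 were scaled by library totals and given exact binomial 95% intervals, which cover counting error only.

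Gene lists were fixed before the data were examined. They numbered 35 and covered m6A factors, mRNA decay, neuronal and synaptic functions, stress and immune responses, ribosomal and respiratory genes, and markers of dentate cell types and of other cells the tissue could hold. A list of Y-linked genes served as a sample check only. The other 34 lists, each with at least 5 tested members, were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, beside camera with an estimated correlation and fry. For each list the members past the false discovery rate over all genes and over the list alone were counted. Named genes followed a rule also fixed before the data were examined. It took Ythdf2 and, per direction, the 10 changed genes with the largest fold and the 5 with the smallest p among those with a mean of at least 1 CPM, a symbol that is not a predicted-gene name and no overlap between the groups. From each list it took up to 4 changed members of smallest p, or up to 2 members as values where none changed. It named 102 genes, of which 72 passed the test and not all are given in the text, and genes named outside it are marked as chosen after their values were seen.

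The alternatives fixed before the data were examined were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (at least 1 CPM in 3 libraries), protein-coding genes only, the replicate number as a block, leaving out each library in turn, limma-trend on log2(FPKM + 0.1) and log2(FPKM + 1), a bound of 1 on the absolute log2 fold change, and a test against a fold of 1.2. Chosen after the data were seen were per-library offsets for GC content and gene length, from a loess fit with a span of 0.3, and the removal of the chromosome 12 segment that holds Efr3b. Transcript features came from GENCODE M21 on GRCm38, which matched 51229 of the table's genes by identifier, 49665 of them with the same start and end, and which covered 98.8% of the changed genes. Bootstrap intervals used 2000 draws.

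The tests were checked on simulated counts for the same 16928 genes with the means, library sizes and dispersions of these libraries, in which 50 genes were changed at each fold. The list of microglial markers was lowered as well, and its members counted as true changes. For the comparison of 3 cKO with 3 Ctrl libraries, edgeR recovered 26% of the genes changed 1.2-fold, 70% at 1.5-fold, 86% at 2-fold and 98% at 4-fold, with 4.64% false calls. Genes were simulated as independent, so the check does not bear on the preset correlation of camera. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.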

Results

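RNA sequencing was used to ask which transcripts of the mouse dentate gyrus differ when the m6A reader YTHDF2 is knocked out in granule cells, the main neurons of this hippocampal region. YTHDF2 binds messages carrying N6-methyladenosine and directs them to deadenylation and decay. The series held 3 libraries labelled cKO and 3 labelled Ctrl, all from total RNA of C57BL/6 dentate gyrus at postnatal day 40. The labels give granule cells as the cell type and dentate gyrus as the tissue and source, and they name no sorting of cells. Gene counts summed to between 16794642 (cKO replicate 2) and 19190101 (Ctrl replicate 3) per library, so that 1 count stood for 0.0521 to 0.0595 CPM (counts scaled to a library total of 1e6). After removal of low counts 16928 genes were tested, with a common biological coefficient of variation of 5.67%. The labels do not say that the replicates came from separate animals, so the p-values measure only the spread between these libraries. Values are TMM-normalised CPM as mean ± SD over the 3 libraries of a group, fold changes are cKO over Ctrl, coordinates are GRCm38 as in the deposited table, and adjusted p-values of single genes are those of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes.

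Ythdf2, the targeted gene (ENSMUSG00000040025, minus strand of chromosome 4 from 132184912 to 132212303), did not pass the test between the groups. Its abundance was 56.8, 56.5 and 54.5 CPM in cKO replicates 1, 2 and 3. Control replicates 2 and 3 held 68.6 and 68.4 CPM, above every cKO library, whereas the library labelled Ctrl replicate 1 held 37.9 CPM, below every cKO library. These levels rested on 635 to 1319 counts per library. The group means were 58.3 ± 17.7 CPM in Ctrl and 55.9 ± 1.29 CPM in cKO, a log2 fold change of -0.06 ± 0.15 (SE) with an edgeR adjusted p of 0.882. An exact two-sided permutation test gave p = 1, where 3 libraries against 3 allow no p below 0.1. The direction depended on single libraries. Without the library labelled Ctrl replicate 1 the log2 fold change of Ythdf2 was -0.29 with an edgeR adjusted p of 0.00951, and without Ctrl replicate 2 or 3 it was 0.06 or 0.07, with adjusted p-values of 0.905 and 0.888, within a range of 0.00951 to 0.985 over the alternatives run for this gene. The counts cover the whole gene and the deleted exons are not given in the sources used here, so they do not separate intact from shortened transcripts. The targeted gene thus went against the label of 1 control library, which was kept in its labelled group in every comparison with Ctrl that follows.

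**Figure D1:**
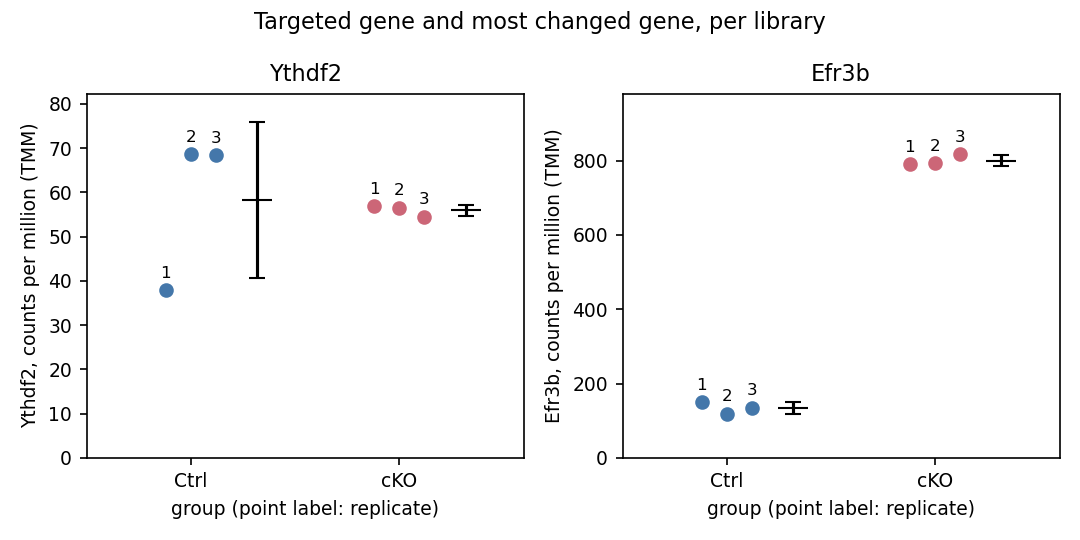
Abundance in CPM (TMM-normalised, linear axes from 0) of Ythdf2 (left) and Efr3b (right) in each library, with the replicate number above each point and black bars for the group mean ± SD (n = 3). Ythdf2 in the library labelled Ctrl replicate 1 lies at 37.9, below the 54.5 to 56.8 of the cKO libraries, while the other controls lie at 68.4 and 68.6, and Efr3b lies between 119 and 149 in the controls and between 790 and 817 in the cKO libraries.

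Efr3b, which encodes a plasma membrane anchor of the phosphatidylinositol 4-kinase complex, had the largest rise and the smallest p among the annotated genes. It rose from 134 ± 15.1 to 800.0 ± 14.9 CPM, a log2 fold change of 2.57 ± 0.06 (SE) or 5.96-fold, with an edgeR adjusted p of 3.42e-12. Several other genes rose by smaller amounts. The anion transporter family member Slc26a10 rose from 59.8 ± 5.42 to 96.7 ± 1.75 CPM (log2 fold change 0.69, edgeR adjusted p = 6.22e-05). Flna, which encodes the actin crosslinker filamin A, rose from 119 ± 4.14 to 169 ± 5.38 CPM (0.51, edgeR adjusted p = 6.22e-05), and both Leng8 (0.51) and Bmp1, a procollagen C-proteinase (0.48), rose with an edgeR adjusted p of 0.000134. The death-domain receptor gene Tnfrsf25 rose from 46.0 ± 10.3 to 84.0 ± 10.4 CPM (0.87, edgeR adjusted p = 0.0012).

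Altogether 668 genes changed by edgeR's test, 3.95% of those tested, of which 520 rose and 148 fell. The median change was 1.24-fold for genes that rose and 0.841-fold for genes that fell. A change of at least 2-fold was found for 19 genes that rose and 6 that fell. The genes with the largest changes are given here among those with a mean of at least 1 CPM, a symbol that is not a predicted-gene name and no overlap between the groups. Besides Efr3b, Tnfrsf25 and Pomc, the largest rises were in Kazn (log2 fold change 1.38), the U6-associated Lsm5 (1.31), Phf11c (1.18), C4a (1.07), the pseudogenes Mid1-ps1 (1.05) and Cdk3-ps (1.00) and the helicase gene Recql4 (0.87). Control means were as low as 0.713 CPM, for Phf11c. The largest falls were in Rpl30-ps10, a processed pseudogene of a ribosomal protein gene (-1.60), the cytosolic DNA sensor Aim2 (-0.76), Pdzrn4 (-0.76), Cdyl (-0.51), the mitochondrial asparagine and cysteine tRNA genes mt-Tn (-0.47) and mt-Tc (-0.43), Zfp804a (-0.45), Sowahc (-0.44), the spliceosomal Snrpg (-0.44) and Lmo1 (-0.41). The tRNA genes mt-Tn and mt-Tc are 71 and 66 bases long, and whether their reads came from mature tRNAs was not examined. The mitochondrial large ribosomal RNA mt-Rnr2 fell from 5764 ± 186 to 4706 ± 99.2 CPM, with a log2 fold change of -0.29 and an edgeR adjusted p of 0.00037. Whether reads were shared between C4a and its paralog C4b, or between Rpl30-ps10 and the other pseudogenes and their parent genes, was not examined, so these values are uncertain. Rpl30 itself, named after its value was seen, stood at 0.13 (edgeR adjusted p = 0.307). Group ranges did not overlap for 664 of the 668 changed genes and for 22.9% of all tested genes, where chance gives 10%. The number of changed genes was 214 (189 rose, 25 fell) without cKO replicate 3, 355 (298 rose, 57 fell) without Ctrl replicate 2, 427 (324 rose, 103 fell) without cKO replicate 2 and 456 (397 rose, 59 fell) without cKO replicate 1. It was 383 (294 rose, 89 fell) after each library was corrected for GC content and gene length, an alternative chosen after the data were seen. Median transcript GC content was 56.6% for the genes that rose, 47.5% for those that fell and 50.1% for all tested genes.

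**Figure D2:**
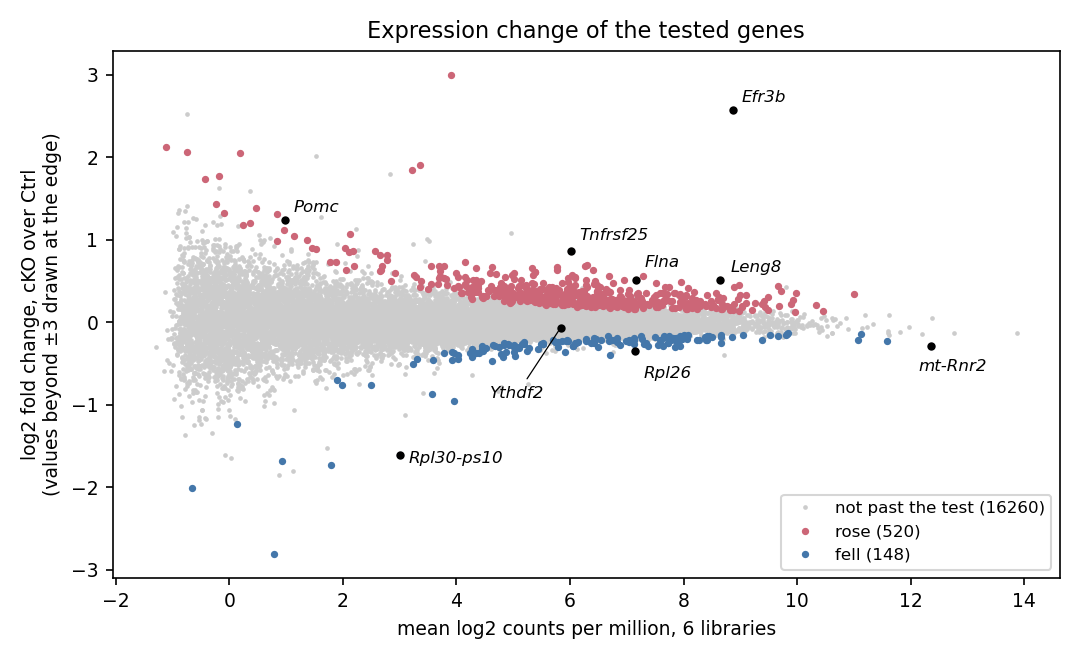
Log2 fold change of cKO over Ctrl (values beyond 3 in either direction drawn at the edge) against the log2 of the mean CPM of the 6 libraries, 1 point per tested gene. The 520 genes that rose are red, the 148 that fell are blue, the other 16260 are grey, and genes labelled by name are black, among them Efr3b at 2.57 and Ythdf2 at -0.06.

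The transcripts next to Efr3b on chromosome 12 were also higher in the cKO libraries. Efr3b lies on the minus strand from 3962554 to 4038915, between Dnmt3a, which ends at 3914443, and Dnajc27, which starts at 4082583. Pomc, the pro-opiomelanocortin precursor gene (plus strand, 3954951 to 3960642), rose from 1.18 ± 0.249 to 2.79 ± 0.221 CPM, a log2 fold change of 1.24 ± 0.24 (SE) with an edgeR adjusted p of 0.0104. An unannotated locus assembled on the plus strand from 3923258 to 3927602, not assigned to any gene in the table, had 1553 counts over the cKO libraries and 1 over the controls, a ratio of 1573 with a 95% counting interval of 282 to 62156 (edgeR adjusted p = 3.57e-11). The processed pseudogene Gm9088 (minus strand, 3931533 to 3932040) had 29 counts in cKO and 0 in Ctrl, too few to be tested. This is a ratio of 9.79 against a floor of 3 counts over the whole control group, with a lower 95% counting limit of 7.47. Gm48001, a transcript antisense to Efr3b on the plus strand, had 95 against 23 counts, a ratio of 4.18 (95% counting interval 2.63 to 6.91). It lies within Efr3b, and without knowledge of strand in the counting the reads of the 2 cannot be told apart. On the flanks the ratio of summed counts was 1.15 for Dnmt3a, a DNA methyltransferase gene that rose with an edgeR adjusted p of 0.0288, and 1.02 for Dnajc27 (adjusted p = 0.761). Of the other 625 tested genes of chromosome 12, 10 rose. The unannotated locus, Gm9088, Gm48001 and the flanking genes were picked after their values were seen, and the intervals and the floor cover counting error only.

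**Figure D3:**
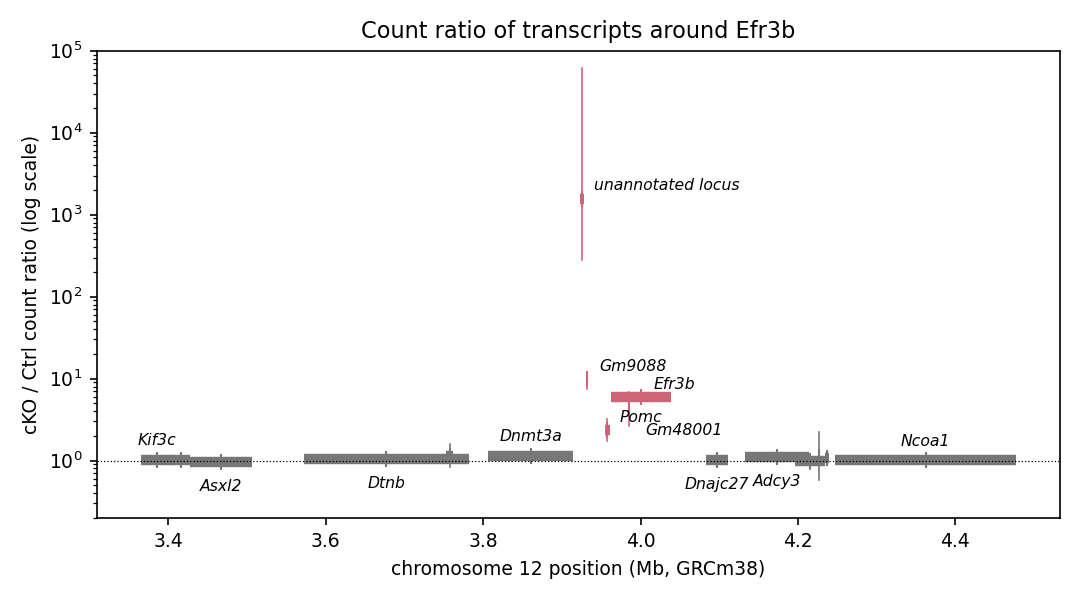
Ratio of cKO to Ctrl counts, scaled by library totals, on a logarithmic axis for transcripts with at least 20 counts between Kif3c and Ncoa1 on chromosome 12 (GRCm38, position in Mb). Each horizontal bar spans a transcript and each vertical line is a 95% counting interval, with transcripts between Dnmt3a and Dnajc27 in red and all others in grey. Ratios of the red transcripts run from 2.37 for Pomc to 1573 for the unannotated locus, and Dnmt3a and Dnajc27 lie at 1.15 and 1.02. Gm9088, with 0 control counts, is drawn at 9.79 against a floor of 3 counts over the control group, with its line reaching down to the lower counting limit of 7.47.

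Ribosomal protein messages were lower in the cKO libraries as a group. Of 77 measured genes 24 fell, 53 did not pass the test and none rose, and 54 fell when adjusted over the list alone. Rpl26 fell from 159 ± 4.20 to 125 ± 3.52 CPM (log2 fold change -0.35, edgeR adjusted p = 0.000584). Rps6 (-0.29), Rps4x (-0.28) and Rpl3 (-0.25) fell with edgeR adjusted p-values of 0.00296 to 0.00445. Rps3a1, which is not a member of the list, fell too (-0.30, edgeR adjusted p = 0.00153). The list's median log2 fold change was -0.19, and camera gave an adjusted p of 5.32e-18 but 0.72 with an estimated correlation. Fry gave 0.163. Subunits of the respiratory chain encoded in the nucleus had a median of -0.09 over 75 genes (-0.06 after the GC and length correction), of which Cox7a2 (-0.24), Atp5g2 (-0.22) and Atp5l (-0.25) fell, 4 genes fell when adjusted over the list alone, and camera gave an adjusted p of 4.38e-06 but 0.819 with an estimated correlation. Fry gave 0.223. None of the 12 mitochondrially encoded messages passed edgeR's test over all genes, 8 had an unadjusted p under 0.05 and fell when adjusted over the list alone, and DESeq2 and limma-voom called 3 and 1. Their median was -0.14, with values of -0.13 for mt-Nd4 and -0.18 for mt-Nd6, but -0.07 without the library labelled Ctrl replicate 1 and -0.06 after the GC and length correction. Camera gave an adjusted p of 0.0134, which was 0.193 without the library labelled Ctrl replicate 1, 0.145 without cKO replicate 1 and 0.351 after the GC and length correction. With an estimated correlation camera's adjusted p for this list was 0.889, and fry gave 0.453. Mitochondrial transcripts took 4.21% to 4.44% of all counts in the cKO libraries and 4.60% to 5.19% in the controls, highest in the library labelled Ctrl replicate 1. Whether reads were shared between ribosomal protein genes and their processed pseudogenes was not examined, so their counts are uncertain.

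Microglial transcripts were lower in cKO, and camera at the preset correlation also called the lists of astrocyte and immature neuron markers lower. All 19 microglial markers had negative log2 fold changes, with a median of -0.24. The fractalkine receptor Cx3cr1 fell from 42.2 ± 0.581 to 33.1 ± 2.61 CPM (log2 fold change -0.35, edgeR adjusted p = 0.00903), the purinergic receptor P2ry12 from 33.0 ± 2.52 to 25.8 ± 0.74 CPM (-0.35, adjusted p = 0.0131), and cathepsin S (Ctss, -0.32) and the complement gene C1qb (-0.31) also fell. In total 6 of the 19 fell over all genes and 13 when adjusted over the list alone. Camera gave an adjusted p of 1.40e-09 and fry 0.0337, against an adjusted p of 0.602 with an estimated correlation in camera. Among 18 astrocyte markers the gap junction gene Gja1 (-0.19), Aldoc (-0.15) and the water channel Aqp4 (-0.21) fell and 15 did not pass. When adjusted over the list alone 7 fell and 1 rose, the median was -0.10, and camera gave an adjusted p of 0.00606 but 0.726 with an estimated correlation. Fry gave 0.174 for the astrocyte list. None of 19 markers of immature granule neurons and progenitors passed edgeR's test, 5 had an unadjusted p under 0.05, none passed when adjusted over the list alone, and DESeq2 and limma-voom called 1 and 0. Their median was -0.15 (-0.09 after the GC and length correction), with -0.19 for Stmn1 and -0.22 for Sox2, and camera gave an adjusted p of 0.00867 but 0.624 with an estimated correlation, and fry gave 0.163. Without the library labelled Ctrl replicate 1 the camera adjusted p of the astrocyte list was 0.0765 and that of the immature neuron list 0.0617. Transcripts of blood cells had a median of -0.63 over 6 genes, but camera did not call this list. Camera's adjusted p was 0.0796, and 0.889 with an estimated correlation, and fry gave 0.571. None of the 6 genes passed edgeR's test, 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom called none. Values were -0.64 for Hbb-bs and -0.61 for Hba-a1, both with overlap between the groups.

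Most genes of the excitatory postsynapse did not pass the test. Of 40 glutamate receptor and postsynaptic density genes 37 did not pass and 3 rose, among them the scaffold gene Shank1 (log2 fold change 0.22, edgeR adjusted p = 0.0264) and the obligatory NMDA receptor subunit gene Grin1 (0.16, adjusted p = 0.0292), and 10 rose when adjusted over the list alone. The median was 0.05, and 0.01 after the GC and length correction. Camera's adjusted p of 0.0392 was 0.602 with an estimated correlation, between 0.0573 and 0.124 without any 1 of the 6 libraries, 0.0532 with the replicate number as a block and 0.567 after the GC and length correction. Fry gave 0.0188 for this list. Of 39 potassium channel genes 5 rose, among them Kcnt1 (0.60), Kcnk9 (0.26) and Kcnip2 (0.20), and Kcnb2 (-0.26) fell, also when adjusted over the list alone, with a camera adjusted p of 0.258. In the list of calcium, CREB and kinase signalling of plasticity Camkk1 (0.16) and Map2k2 (0.20) rose while 3 genes fell, among them the kinase gene Prkacb (-0.18) and the calcineurin subunit gene Ppp3ca (-0.14), out of 38 genes. When adjusted over the list alone 3 rose and 8 fell, and camera's downward test had an adjusted p of 0.0563, and of 0.00549 after the GC and length correction, but 0.726 with an estimated correlation and no GC and length correction. The synaptic vesicle priming gene Unc13a (0.24) was the only one of 30 presynaptic genes to rise over all genes, and 1 rose and 1 fell when adjusted over the list alone (limma's camera adjusted p = 0.743, but 0.0296 after the GC and length correction, downward, and 0.926 with an estimated correlation without that correction). Scg2, a secretogranin of dense-core vesicles (-0.21), fell among 22 neuropeptide and vesicle genes, as it did when adjusted over the list alone (limma's camera adjusted p = 0.672). Kcnb2 and Map2k2 were named after their values were seen.

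Markers of mature granule cells showed no common direction. Of 24 measured markers Pitpnm2 rose from 882 ± 15.7 to 1062 ± 28.1 CPM (log2 fold change 0.27, edgeR adjusted p = 0.000908) and Stxbp6 fell from 268 ± 19.7 to 220 ± 5.84 CPM (-0.29, adjusted p = 0.00554), with 1 up and 2 down when adjusted over the list alone, a median of -0.01 and a camera adjusted p of 0.796. Among markers of neighbouring neurons 1 gene rose in each of 3 lists, Csf2rb2 of mossy cells (0.69), Fibcd1 of CA1 (0.30) and Cdh24 of CA2 and CA3 (0.55). When adjusted over the list alone 1 mossy cell marker rose, 1 CA1 marker rose and 1 fell, and 3 markers of CA2 and CA3 rose and 1 fell, with camera adjusted p-values of 0.852, 0.75 and 0.75. Among 13 genes of reactive glia Serpina3n (0.22) rose and C4b (-0.35) fell, with 1 up and 3 down when adjusted over the list alone (limma's camera adjusted p = 0.457).

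Messages for the machinery that removes poly(A) tails and decays mRNA included 4 genes that rose, out of 33 and also when adjusted over the list alone. The poly(A) nuclease gene Pan2 rose from 32.7 ± 1.56 to 42.9 ± 3.53 CPM (log2 fold change 0.39, edgeR adjusted p = 0.00679), and the CCR4-NOT subunit genes Cnot3 (0.28) and Cnot10 (0.21) and the decapping scaffold gene Edc4 (0.23) rose too, while the list's median was -0.02 and camera's adjusted p 0.903. None of 19 m6A writers, erasers and other readers passed edgeR's test over all genes or over the list alone, 3 had an unadjusted p under 0.05, DESeq2 and limma-voom called none, and the demethylase gene Fto stood at -0.12 and Hnrnpc at -0.12 (camera adjusted p = 0.796). The guidance genes Plxna3 (0.38) and Slit1 (0.23) rose among 53 genes of axon growth (limma's camera adjusted p = 0.796), the dishevelled genes Dvl1 (0.29) and Dvl2 (0.37) among 38 of Wnt signalling (0.75), the interferon signalling genes Irf9 (0.60) and Stat2 (0.27) among 24 interferon-stimulated genes (0.796) and the heat shock transcription factor gene Hsf1 (0.33) among 27 genes of protein folding stress (0.796). When adjusted over the list alone these 4 lists had 2, 2, 2 and 1 genes that rose, and 2 Wnt genes fell. Median, mean and test differed in sign for 5 lists. The m6A factors and the decay machinery had medians of -0.02 with means of 0.00 and 0.01 and a downward camera test, interferon genes had a negative median and an upward fry test, the folding stress list had a median of 0.00 and a mean of 0.02 with a downward camera test, and CA2 and CA3 markers had a median of -0.08 with an upward camera test.

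No member passed edgeR's test in 15 of the 35 lists, which together held 239 tested genes, of which 31 had an unadjusted p under 0.05, DESeq2 called 4 and limma-voom called 1. Beyond those given above they were the immediate early genes (29 tested, Atf3 at -1.01 and Npas4 at 0.51), cell cycle genes (31, Mcm3 at -0.56 and Mcm6 at -0.17), markers of GABAergic interneurons (22, Vip at 0.48 and Slc32a1 at 0.15), of thalamic neurons (10, Rora at -0.22 and Synpo2 at 0.21), of oligodendrocytes (21, Trf at -0.54 and Cnp at -0.12) and of their precursors (14, C1ql1 at 0.38 and Cspg4 at 0.19). The remaining ones were markers of endothelium (18, Ly6c1 at 0.30 and Ly6a at 0.33), pericytes and smooth muscle (12, Cspg4 at 0.19 and Anpep at 0.66), choroid plexus (7, Aqp1 at 0.77 and Prlr at 0.33), ependyma (6, Rarres2 at -0.61 and Foxj1 at 0.41) and meningeal fibroblasts (13, Slc6a13 at -0.44 and Col1a2 at -0.30). In these 11 lists and for blood transcripts no member passed when adjusted over the list alone, and the lowest camera adjusted p was 0.0563, for endothelium. Of 4 tested Y-linked genes, which were expressed in all 6 libraries, Kdm5d rose (0.22, edgeR adjusted p = 0.0487), and 2 rose when adjusted over the list alone.

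**Figure D4:**
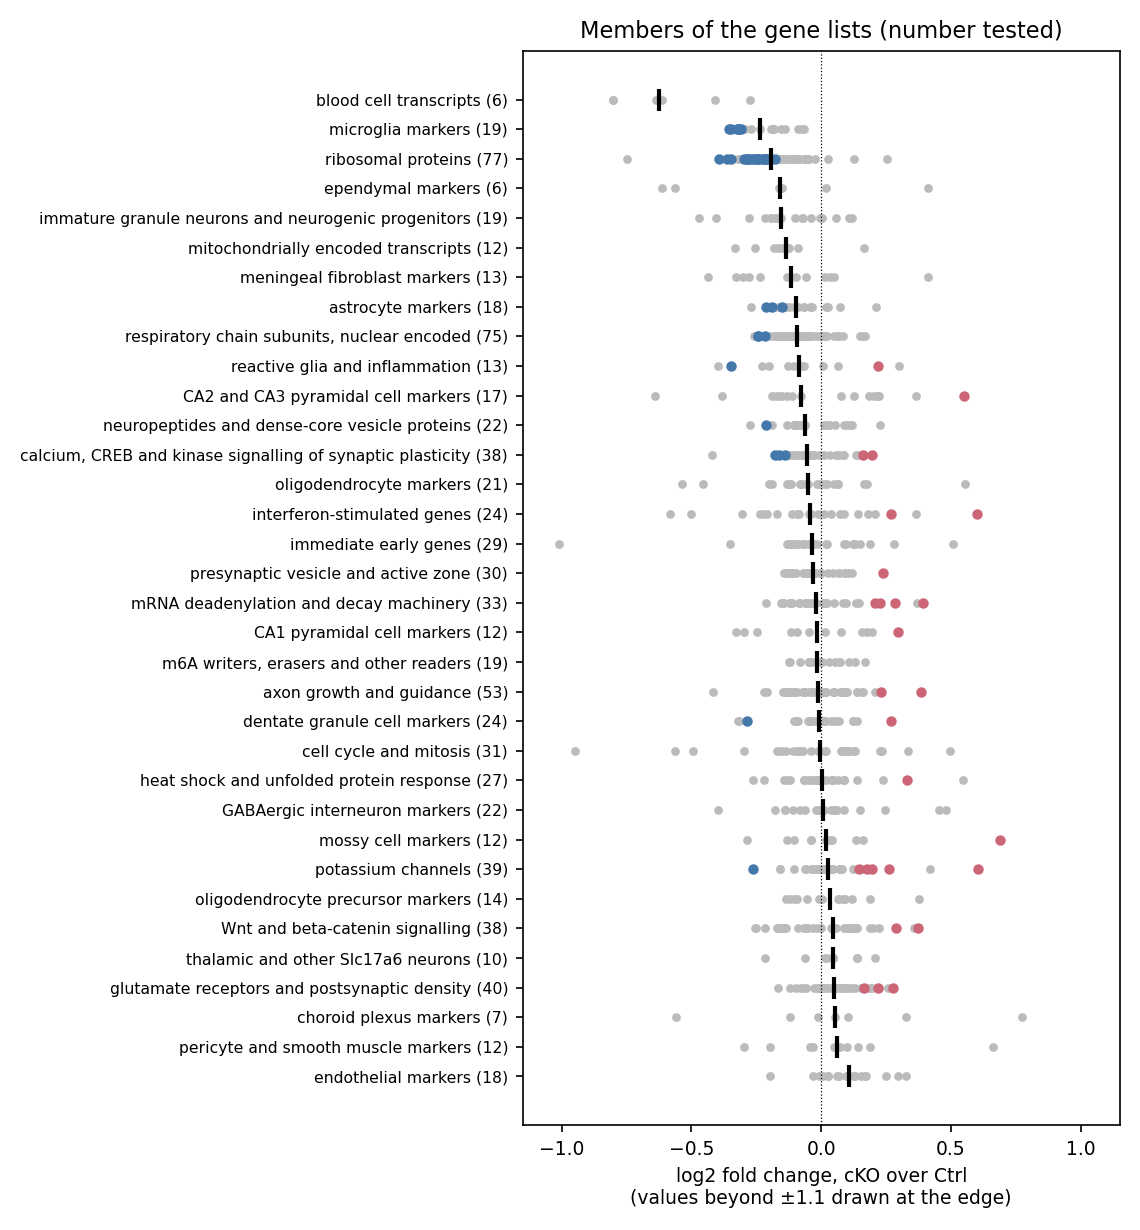
Log2 fold change of cKO over Ctrl (values beyond 1.1 in either direction drawn at the edge) for the members of 34 gene lists, 1 point per tested gene, with the number tested in parentheses. Genes that rose are red, genes that fell are blue, others are grey, and the black tick is the list median, which runs from -0.63 for blood cell transcripts to 0.11 for endothelial markers.

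Across the 34 lists tested with camera at a preset correlation of 0.01, 7 passed, of which 6 were lower and only the glutamate receptor and postsynaptic density list was higher. After the GC and length correction 8 passed in camera, of which 7 were lower and only the endothelial list was higher (adjusted p = 0.0159, against 0.0563 before). The glutamate receptor and mitochondrially encoded lists then no longer passed, and the presynaptic and the calcium, CREB and kinase lists did. With an estimated correlation none passed, 2 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.602, and fry called 2 lists. Several named genes overlap another counted gene, among them Efr3b, Slc26a10, Leng8, Recql4, Aim2, Snrpg, Rpl3, Cx3cr1, P2ry12, Grin1, Shank1, Unc13a, Cnot3, Dvl1, Dvl2, Irf9 and Pitpnm2, and their counts are uncertain because the use of strand in the counting is not given in the sources used here.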

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

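The tests on chromosome 12 in this part were chosen only after the result was seen. Among 14076 genes with counts that were too low to be tested, 2 stood out because they had at least 3 counts in every library of 1 group and 0 in the other. Gm9088, the processed pseudogene on chromosome 12 from 3931533 to 3932040, had 12, 10 and 7 counts in cKO replicates 1, 2 and 3, in total 29, and 0 in the controls. Psmb11, a proteasome subunit gene on the plus strand of chromosome 14 from 54621433 to 54629556, had 5, 3 and 6 counts in Ctrl replicates 1, 2 and 3, in total 14, and 0 in the cKO libraries. Groups of 3 libraries were not tested for single libraries that stand apart.

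Gm9088 lies within a stretch of chromosome 12 in which every transcript with at least 10 counts was higher in the cKO libraries, from the unannotated locus through Pomc to Efr3b. Release of the Efr3b message from decay is argued against as the sole explanation by the other transcripts of the segment. Of these 4, on both strands, 4 also had ratios whose 95% counting intervals lay above 1.5. However, Gm48001 overlaps Efr3b and may hold its reads. The others lie downstream of Efr3b, and whether reads ran on past its end was not examined. Extra genomic copies of the segment in the cKO mice could contribute to the group of changes: the lowest ratio inside it was 2.37, for Pomc, and the higher of the 2 flanking genes was 1.15, for Dnmt3a. But the ratios were unequal, with 4.18 for Gm48001, 5.96 for Efr3b and 1573 for the unannotated locus. More copies alone, with the expression of each copy unchanged, would not give such unequal ratios. A hypothesis is that a transgene built on a genomic segment around Pomc, as is used to drive Cre recombinase in dentate granule cells, was carried by the cKO mice only, but the labels name no driver line and genomic DNA was not analysed here. An effect of YTHDF2 loss on Efr3b itself in addition to this stays open. Removal of the segment took out only its 4 tested genes and left 664 genes changed. It cannot show whether those changes come from YTHDF2 loss or from anything else that only the cKO mice carried.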

How the results depend on the processing

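The correction for GC content and length and the removal of the chromosome 12 segment were chosen after the data were seen. The 668 changed genes (520 rose, 148 fell) became 651 with RLE and 670 with upper-quartile scaling, 803 with DESeq2, 655 with limma-voom, 710 with the stricter filter, 755 with protein-coding genes only and 664 without the segment, and most rose under each. They became 1155 (729 rose, 426 fell) with no low-count filter, 383 with the GC and length offsets, 110 on log2(FPKM + 0.1), 95 on log2(FPKM + 1), 25 with an absolute log2 fold change of at least 1 and 27 when tested against a fold of 1.2. The last 2 are stricter by construction, and the cause was not tested for the others. Leaving out 1 library gave 214 to 535, with 214 without cKO replicate 3, 355 without Ctrl replicate 2, 427 without cKO replicate 2 and 504 without the library labelled Ctrl replicate 1, in fits with fewer samples. The log2 fold change of Ythdf2 went from -0.29 (adjusted p = 0.00951) without the library labelled Ctrl replicate 1 to 0.069 without Ctrl replicate 3, and 0.06 without Ctrl replicate 2. It stayed negative and not past the test in every other setting run, with edgeR, DESeq2 or limma adjusted p-values up to 0.985. The 7 lists called by camera became 0 with an estimated correlation, 2 with fry, 10 on ranks and 5 to 9 elsewhere. Ribosomal, respiratory and microglial lists kept their camera calls under every scaling, filter and left-out library, all lower in cKO, and camera was not run beside DESeq2 or FPKM. Of 72 named genes past the test, 70 stayed past it with RLE and with upper-quartile scaling, 26 to 55 without 1 library, 42 with GC and length offsets and 14 on each FPKM scale, and 60 of the 61 with an adjusted p from DESeq2, and none reversed. At 1.5-fold, limma-trend on FPKM recovered 48% of simulated changes and edgeR 70%. At 1.2-fold edgeR recovered 26% of simulated changes. In the simulation edgeR called 151 genes, against 668 in these data, so its recovery there need not hold here.

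With the replicate number as a block (replicate block), 808 genes changed, 7 lists were called and Ythdf2 stood at -0.03. The glutamate receptor list then had a camera adjusted p of 0.0532. Among the settings given for this list, camera's adjusted p ran from 0.00326 with limma-voom to 0.602 with an estimated correlation. It was 0.567 with GC and length offsets. Deviations of same-numbered libraries correlated at 0.09, 0.01 and 0.00 for replicates 1, 2 and 3, the first being the highest of all pairs. Pairs of unlike number ran from -0.08 to 0.08, highest for cKO replicate 2 with Ctrl replicate 3. Correlations this weak cannot decide whether a shared number marks anything more.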

Other observations

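Tests on the library labelled Ctrl replicate 1, the GC and length correction and the count of changed genes over other splits were chosen only after the results were seen. By edgeR's test against a fold of 1.2, 27 genes differed from controls by more than that fold, of which 26 rose and 1, Rpl30-ps10, fell. Efr3b, the unannotated locus beside it, Slc26a10, Flna, Leng8, Bmp1 and Tnfrsf25 were among them. The set also held genes not described above, such as genes of RNA processing and transcription, with the nuclear poly(A)-binding protein gene Pabpn1 (log2 fold change 0.57, adjusted p against that fold 0.0211 by edgeR), the SR protein gene Clasrp (0.51) and the snRNA-activating complex gene Snapc4 (0.54). It also included genes of cell contact and guidance, with the receptor gene Robo3 (66.5 ± 4.94 to 103 ± 9.01 CPM, 0.63, adjusted p against that fold 0.0168 by edgeR), the metalloprotease gene Adam8 (0.66), thrombospondin 3 (Thbs3, 0.63) and the focal adhesion adaptor paxillin (Pxn, 0.57). These genes were picked after their values were seen, and no enrichment of these themes was tested.

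Ythdf2 did not pass the test between the groups, with 37.9 CPM in the library labelled Ctrl replicate 1. A swap of that library with a cKO library is argued against by Efr3b, at 149 CPM in it and at least 790 CPM in every cKO library, while a single wrong label from outside these groups was not excluded. Its Ythdf2 level was 0.553 of the mean of the other controls (95% interval from counting error and common biological variation 0.47 to 0.65). The interval may be too narrow, since the biological coefficient of variation was 12.8% for Ythdf2 against 5.67% in common. The level is of the size that silence of 1 of 2 gene copies could give. But the idea came from this value and no genotype is labelled, so it cannot be told apart from other losses. Without that library, left out here because its Ythdf2 value was the lowest, which itself moves the difference downward, Ythdf2 stood at -0.29 (95% interval -0.40 to -0.18), and the reads in the cKO libraries may come from cells without the deletion or from exons outside it, which cannot be told apart because neither the recombined share nor the deleted exons are given in the sources used here. Loss of YTHDF2 itself, the difference the groups are labelled by, stays open.

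More genes rose than fell in cKO, and the genes that rose were richer in GC. With offsets for GC content and length, the Spearman correlation of log2 fold change with GC content across genes went from 0.23 to 0.006. Of the 383 genes then called changed 76.8% rose, against 77.8% of 668 before. This argues against a GC or length trend between libraries as the whole cause of the excess of rises. Still, fewer genes passed and the folds were smaller. The median log2 fold change of the genes that rose was 0.25 (bootstrap 95% interval 0.24 to 0.27) against 0.31 before. That median cannot decide the cause, since these genes were picked by their rise in the same data. Release of m6A-rich messages from decay was examined only through exon junction density, a proxy, since m6A is depleted near junctions. The 483 protein-coding genes that rose had a median of 4.88 junctions per kb. Unchanged genes matched on GC, length and expression had 3.31. The difference of 1.57, whose bootstrap 95% interval excluded 0 and reached 1.89, was opposite to the lower density predicted for such release. It cannot decide the question, because m6A itself was not measured, so release stays open. Retention of introns could be a candidate source for the genes that rose. Of their exon bases 7.24 percentage points more lay only in retained-intron transcripts than in matched genes (5.13 to 9.50). But the genes that fell also had 5.87 points more (1.17 to 10.7), so retention cannot be told apart without reads over introns. Whether single genes among those that rose respond to YTHDF2 was not tested.

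The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For changed genes the real split gave 668 and the highest other split 3, so that 1 of the 10 gave as many. For gene lists called by camera at the preset correlation the real split gave 7, and 3 of the 10 splits gave as many, the highest other being 13 when cKO replicates 1 and 3 and Ctrl replicate 2 were set against the rest.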
